A study of Mus musculus with 48 samples.

How the data were processed

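PolyA RNA of 28 tumors, 13 derived cell lines and 7 normal livers of C57BL/6 mice was sequenced, 1 library per sample. For each library the deposited file lists a length, an effective length, a TPM and an estimated count for each of 58083 transcripts. The authors' quantification tool is not given in the sources used here. The submitters' processing notes name the build GRCm38 and FastQC 0.11.8. The TPM values summed to 1e+06 in each file and served, with effective lengths, only for length offsets.

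Transcripts were joined to genes by the GENCODE annotation of GRCm38, which matched 57473 and left 610 out, with a median of 0.265% and at most 0.399% of reads. For 99.7% of matched transcripts the deposited length lay within 3 bases of the coding length, so untranslated regions were not counted and noncoding genes such as H19 were not measured. Estimated counts were summed to 22195 genes and rounded. Copies of 1 library under 2 labels were checked for by the chi-square per degree of freedom between replicates. It was lowest in CTNNB1;Tert lines 2 and 3 (8.57, other pairs of lines 228.6 or more). The labels of MYC;sg-p53 conflict: for the library labelled tumor replicate 2 and the library labelled cell line replicate 2 the name of the deposited file gives the other tissue. Both were left out. For MYC;sg-p53 tumor replicate 3, which was used, and cell line replicate 1 it gives the same tissue with the number of another animal of the genotype.

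Counts were tested in R 4.3.3 with edgeR 4.0.16 by a quasi-likelihood F test, with filterByExpr, TMM scaling and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. All tests were two-sided. A first fit held the 27 tumors and 7 normal livers (16140 genes). A second held 11 lines and 16 tumors of the 5 genotypes with at least 2 usable libraries of each (16066 genes). Each group had its own mean, and contrasts over several genotypes weighted these equally. The 22 comparisons, the lists, the tests and the rule for naming genes were fixed before the data were examined. The p-values measure the spread between samples, while floors cover counting error only. Where 1 side had no reads, a fold is a lower bound against a floor of 3 counts over that group. CPM values use TMM library sizes, and scores add 0.5 CPM before the log.

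The 31 lists were drivers, Wnt feedback, pericentral, periportal, hepatocyte, bile acid, oncofetal, biliary progenitor, Notch, YAP, proliferation, ribosome biogenesis, p53 targets, glycolysis, lipid synthesis, acute phase, interferon and antigen presentation, immediate early, T and NK cell, B and plasma cell, macrophage, neutrophil, endothelial, stellate and matrix, mesenchymal, red cell, pancreatic acinar, adipocyte, male-biased liver, female-biased liver and Y-linked. The 30 besides drivers were tested by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 660 tests 250 were called, and 0 held with an estimated correlation, where the smallest adjusted p was 0.0522. The Y-linked list, of 4 genes, was called in 0 of 22 comparisons, which does not show that sex was balanced. Its mean log2 CPM was below 0 in each myc-luc-bcat, myc-lucOS-bcat and MYC;Tert tumor. With members without counts at their bound, its median log2 change was -9.32 for myc-lucOS-bcat and -10.7 for MYC;Tert against normal liver. Set against MYC;Tert, it was 9.61 for MYC;CTNNB1 and 10.7 for CTNNB1;Tert. Genes were named by rule: the 5 largest changes each way (2 for a single genotype against normal liver) at an adjusted p under 0.05 and 5 CPM on the higher side, without overlap of the sides, up to 4 called members of each called or preset list (2 where this exceeded 30 genes), and the drivers. Predicted and clone names were passed over.

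On simulated counts with 200 changed genes edgeR recovered 9% of 2-fold and 57% of 4-fold changes between MYC;CTNNB1 and MYC;sg-Axin1 and called 0 unchanged genes (DESeq2 34). Between lines and tumors it recovered 52% and 77% and called 9 unchanged genes (DESeq2 107). Camera called 0 of 20 lists of unchanged genes. Titles share animal numbers between tumors and lines. In 9 pairs with a choice of line the correlation across genes of tumor and line from 1 animal, after removing genotype means, was 0.338, 0.114 and 0.159 for CTNNB1;Tert. With 2 pairs in a genotype both have the same value by construction, which was 0.431 for MYC;CTNNB1, 0.0224 for MYC;sg-Kmt2b and 0.0298 for MYC;sg-Kmt2c. Genes are not independent replicates, and the animal entered only as a block in 10 animals.

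Alternatives were size factors of DESeq2, no filter on low counts, transcript length offsets, a term for an S index in the title, only the groups of a contrast fitted, the MYC;sg-p53 libraries as labelled, DESeq2 1.42.0, voom with quality weights, each library left out, the animal block and an estimated correlation. Chosen after seeing the data were a term for Y-linked reads, a fit without normal liver 4, CTNNB1;Tert tumor 2 and MYC;sg-Axin1 tumor 2, and the 20 libraries of the 10 animals without the animal term. Of 48 libraries 25 had Eif2s3y above 5 CPM, among them 4 of 7 normal livers. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.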

Results

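The series holds 48 polyA RNA libraries from C57BL/6 mice given tumor drivers by hydrodynamic tail-vein injection, a method that delivers plasmids to hepatocytes. They form 16 groups: 28 tumors of 9 genotypes, 13 cell lines of 6 of these genotypes, grown for 8 to 10 passages, and 7 normal livers. Each tumor genotype had 3 libraries, except MYC;sg-Kmt2b with 4, and each line genotype had 2, except CTNNB1;Tert with 3. MYC, CTNNB1 (beta-catenin, the effector of Wnt signaling) and Tert (telomerase) are drivers, and the prefix sg marks a gene targeted by a guide RNA. In myc-luc-bcat and myc-lucOS-bcat, luc is read here as luciferase and bcat as beta-catenin. Totals ran from 21.4 to 47.6 M reads per library with a median of 34.2 M, apart from normal liver replicate 4 with 2.30 M. The series title concerns how combined drivers shape differences between tumors. On GRCm38 Myc (ENSMUSG00000022346.15) lies on chromosome 15 from 61985391 to 61990374. Likewise Ctnnb1 (ENSMUSG00000006932.17) lies on chromosome 9 from 120929216 to 120960507, and Tert (ENSMUSG00000021611.9) on chromosome 13 from 73626911 to 73649843. Among targeted genes are Axin1 (ENSMUSG00000024182.16) on chromosome 17 from 26138688 to 26195811, and Kmt2b (ENSMUSG00000006307.16) on chromosome 7 from 30568858 to 30588726. The others are Kmt2c (ENSMUSG00000038056.15) on chromosome 5 from 25271798 to 25498783, and Trp53 (ENSMUSG00000059552.13) on chromosome 11 from 69580359 to 69591873. Levels are counts scaled to 1e+06 per library (CPM). Log2 changes stand with ± their standard error, then the adjusted p of edgeR, then the number of tumors or lines on the first side that lay beyond every library of the other side.

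Of the targeted genes Trp53, which encodes p53, stood at 20.99 and 28.8 CPM in MYC;sg-p53 tumor replicates 1 and 3, while tumors of other genotypes ran from 36.7 to 154 CPM. It was 30.4 CPM in the library labelled MYC;sg-p53 tumor replicate 2. The MYC;sg-p53 line 1 had 23.3 CPM and the library labelled MYC;sg-p53 cell line replicate 2 had 30.7 CPM, against 76.0 to 328 CPM in other lines. Kmt2c, a histone H3K4 methyltransferase, was at 57.8, 53.7 and 36.6 CPM in its 3 tumors and 11.3 and 17.1 CPM in its lines (normal liver 52.1 to 84.2). Kmt2b, a related methyltransferase, was at 43.5, 62.6, 91.9 and 60.3 CPM in its 4 tumors and 71.9 and 76.7 CPM in its lines (normal liver 61.9 to 91.0). Axin1, a scaffold of the complex that degrades beta-catenin, was at 40.5, 34.3 and 43.1 CPM in its tumors and 63.4 and 70.97 CPM in its lines (normal liver 32.3 to 46.1). A guide RNA edit can leave transcript levels as they are. Tert reached 4294, 232 and 1000.5 CPM in CTNNB1;Tert tumors and 228, 85.1 and 381 CPM in MYC;Tert tumors, against 9.18 to 25.04 CPM in normal liver. Myc ranged from 2.82 to 16.7 CPM in normal liver and was 40.6, 45.7 and 21.96 CPM in CTNNB1;Tert tumors. It reached 432, 1069 and 368 CPM in MYC;CTNNB1 tumors. Ctnnb1 stood at 2134, 2190.5 and 2147 CPM in myc-luc-bcat, 1983, 2834 and 2497 CPM in myc-lucOS-bcat and 806, 1258 and 871 CPM in MYC;CTNNB1 tumors. The counts do not separate a delivered copy from the mouse gene. Only mouse transcripts were counted, so reads of a human copy, if one was delivered, would be counted in part at most.

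**Figure D1:**
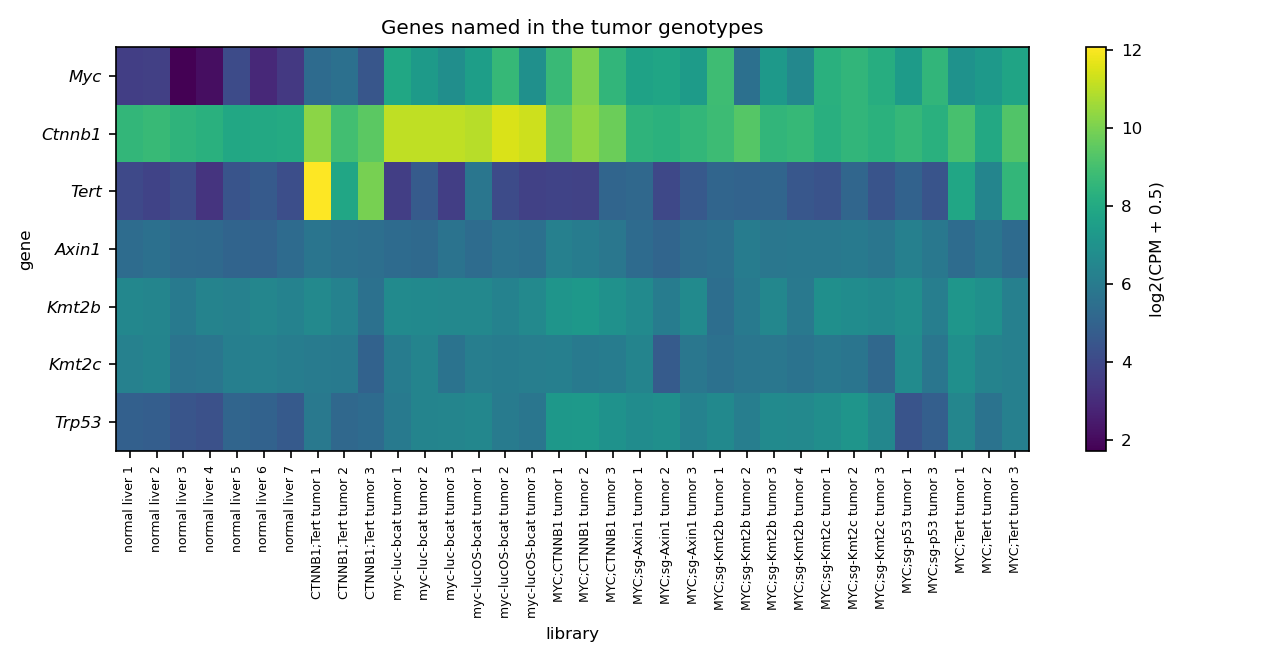
Levels of the 7 genes named in the genotypes, as log2(CPM + 0.5), in each normal liver and each tumor used, 1 column per library. Tert is highest in CTNNB1;Tert tumor 1 (4294 CPM) and Ctnnb1 in myc-lucOS-bcat tumor 2 (2834 CPM).

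Across the 27 tumors used, weighted equally by genotype, genes of cell division rose and genes of mature hepatocytes fell against the 7 normal livers. Psat1 and Phgdh, enzymes of serine synthesis, rose (log2 6.64 ± 0.56, adjusted p = 1.75e-10, 27 of 27, and log2 6.74 ± 0.59, adjusted p = 3.6e-10, 27 of 27). So did Igf2, a fetal growth factor (log2 7.83 ± 0.92, adjusted p = 5.24e-08, 27 of 27). The major urinary protein gene Mup17, active in adult hepatocytes, fell by 12.77 ± 0.92 (adjusted p = 7.77e-11, 27 of 27). Cdk1, the kinase that starts mitosis, went from 3.02 to 79.4 CPM (log2 4.64 ± 0.27, adjusted p = 3.35e-13, 27 of 27). Among 25 proliferation genes 25 rose (25 adjusted over the list alone, median log2 change 4.78, camera adjusted p = 8.11e-20, adjusted p = 0.251 with an estimated correlation). Npm1, a nucleolar chaperone, rose (log2 2.53 ± 0.22, adjusted p = 3.76e-10, 26 of 27). Of the 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone, median log2 change 1.79, camera adjusted p = 9.72e-11, adjusted p = 0.325 with an estimated correlation). The antitrypsin gene Serpina1c fell by 5.25 ± 0.53 (adjusted p = 3.99e-09, 27 of 27). Among the 25 hepatocyte genes 24 fell (24 adjusted over the list alone, median log2 change -3.62, camera adjusted p = 1.47e-09, adjusted p = 0.49 with an estimated correlation). Of 15 oncofetal genes 11 rose (11 adjusted over the list alone, median log2 change 3.74, camera adjusted p = 0.00171, adjusted p = 0.319 with an estimated correlation). B2m, the light chain of class I antigen presentation, fell by 2.73 ± 0.21 (adjusted p = 2.84e-11, 25 of 27). Among 25 interferon and antigen presentation genes 1 rose and 17 fell (1 rose and 17 fell when adjusted over the list alone, median log2 change -1.60, camera adjusted p = 5.77e-06, adjusted p = 0.504 with an estimated correlation). CTNNB1;Tert tumors did not share this fall (list means 6.01, 5.12 and 5.36, normal liver 4.68 to 5.47), from which cell content was not separated. Of the 11 male-biased liver genes 11 fell (11 adjusted over the list alone). The test of edgeR called 5007 genes higher and 4373 lower of 16140. The median over all genes was 0.18 here, and 0.18 for CTNNB1;Tert, 0.26 for MYC;CTNNB1, 0.10 for MYC;sg-Kmt2b and 0.30 for MYC;Tert against normal liver.

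**Figure D2:**
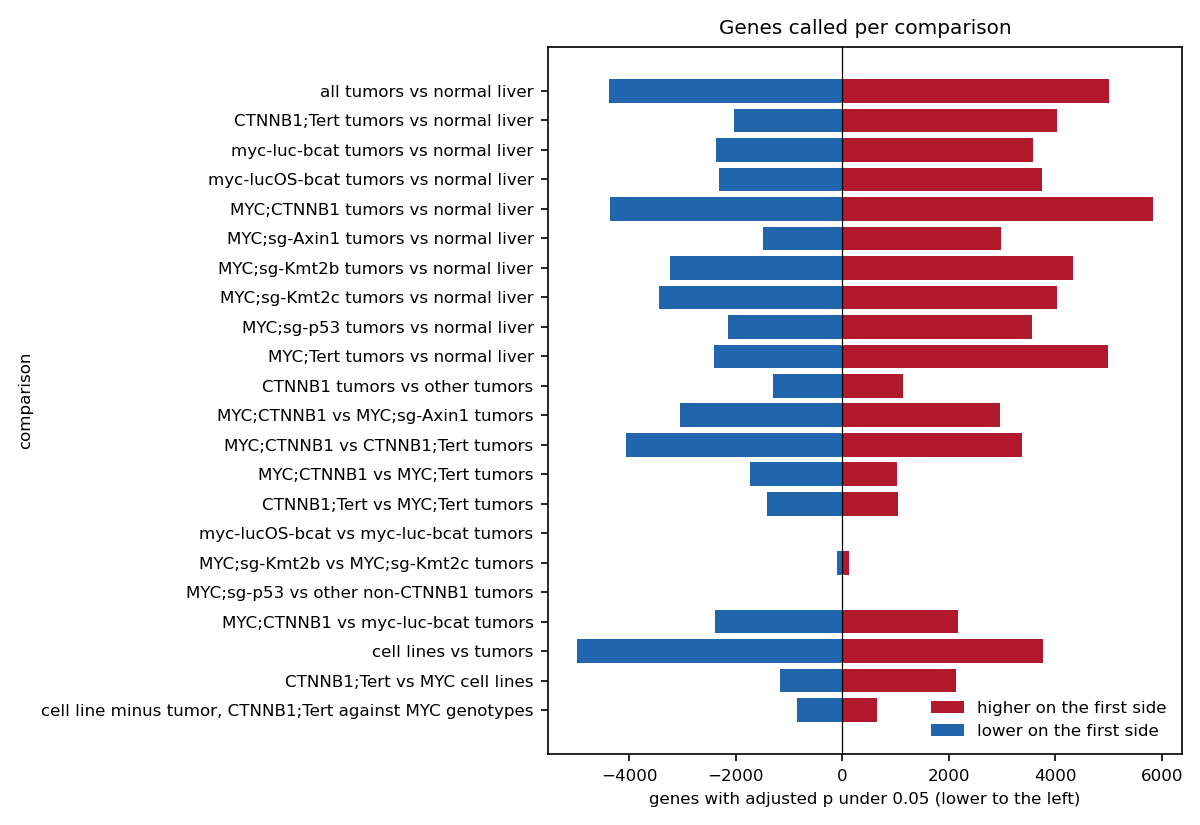
Number of genes with an adjusted p under 0.05 (x axis) in each of the 22 comparisons (y axis), higher on the first side to the right and lower to the left. The bars run from 0 genes for myc-lucOS-bcat against myc-luc-bcat to 5839 higher and 4361 lower for MYC;CTNNB1 against normal liver.

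CTNNB1;Tert tumors had high mesenchymal and low periportal genes against normal liver, and 1 of the 3 carried most of a rise of neutrophil genes. Tert rose from 17.1 to 1842 CPM (log2 6.73 ± 0.59, adjusted p = 1e-08, 3 of 3), and Myc, not delivered here, reached 36.1 CPM (log2 1.89 ± 0.50, adjusted p = 0.00407, 3 of 3). Anxa2, a membrane-binding annexin, rose (log2 5.80 ± 0.47, adjusted p = 4.46e-09, 3 of 3). Among the 16 mesenchymal genes 11 rose (11 adjusted over the list alone, median log2 change 3.39, camera adjusted p = 0.000285, adjusted p = 0.338 with an estimated correlation). Cxcr2, a chemokine receptor of neutrophils, rose (log2 5.61 ± 0.98, adjusted p = 7.43e-05, 3 of 3). Of 13 neutrophil genes 11 rose (13 adjusted over the list alone, median log2 change 5.61, camera adjusted p = 0.000708, adjusted p = 0.527 with an estimated correlation). The neutrophil mean was 0.80, 4.39 and 0.75 in tumors 1, 2 and 3. Without tumor 2, normal liver 4 and MYC;sg-Axin1 tumor 2 there were 2 neutrophil genes called higher of 12 and 7 mesenchymal genes of 16. The glutaminase gene Gls2 was at 11.6 against 825 CPM (log2 -6.16 ± 1.06, adjusted p = 6.18e-05, 3 of 3). Among 16 periportal genes 13 fell (13 adjusted over the list alone, median log2 change -4.67, camera adjusted p = 3.56e-09, adjusted p = 0.207 with an estimated correlation). Of 25 hepatocyte genes 9 fell and of 25 proliferation genes 21 rose (9 and 23 adjusted over each list alone). Of 20 ribosome biogenesis genes 2 rose and 1 fell (0 adjusted over the list alone). Ly6d, a surface antigen, reached 1418 CPM (log2 10.98 ± 1.52, adjusted p = 3.9e-06, 3 of 3), and of 15 oncofetal genes 11 rose (11 adjusted over the list alone). Calls numbered 4035 higher and 2025 lower, 3324 in all without CTNNB1;Tert tumor 2, and 3261 without it, normal liver 4 and MYC;sg-Axin1 tumor 2. That tumor had 1905 CPM of Vim, 726 CPM of C1qa and 2453 CPM of Alb, markers of mesenchyme, macrophages and hepatocytes.

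In myc-luc-bcat tumors growth genes rose and interferon and antigen presentation genes fell. Titles of both luc groups carry a prefix that no other library has, so a batch and these genotypes cannot be told apart. Ctnnb1 was at 2157 against 316 CPM (log2 2.85 ± 0.26, adjusted p = 1.97e-09, 3 of 3) and Myc at 171 against 9.29 CPM (log2 4.26 ± 0.51, adjusted p = 2.43e-07, 3 of 3). The mitotic kinase gene Aurka rose (log2 5.12 ± 0.32, adjusted p = 2.36e-12, 3 of 3), and of 25 proliferation genes 25 rose (25 adjusted over the list alone). Dkc1, a pseudouridine synthase of the nucleolus, rose (log2 2.50 ± 0.25, adjusted p = 1.36e-08, 3 of 3), and of 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone). B2m fell by 3.28 ± 0.46 (adjusted p = 3.17e-06, 3 of 3). Of 25 interferon and antigen presentation genes 15 fell (16 adjusted over the list alone, median log2 change -1.81, camera adjusted p = 6.74e-08, adjusted p = 0.555 with an estimated correlation). Macrophage genes moved the same way in the mean (3.44, 3.47 and 3.398 against 3.65 to 5.198 in normal liver), their list not called (camera adjusted p = 0.31), so cell content is not separated from this fall. Among 11 B and plasma cell genes 7 fell (8 adjusted over the list alone, median log2 change -3.23, or -3.03 with members without counts on one side at their bound, camera adjusted p = 0.0181, adjusted p = 0.77 with an estimated correlation). Transthyretin (Ttr) went from 9420.5 to 432 CPM (log2 -4.36 ± 1.01, adjusted p = 0.00128, 3 of 3), and of 25 hepatocyte genes 15 fell (18 adjusted over the list alone). Igf2 rose (log2 9.04 ± 1.03, adjusted p = 1.17e-07, 3 of 3), while of 15 oncofetal genes 7 rose (7 adjusted over the list alone). Scgb1a1, a secretoglobin of airway club cells, had no reads in the 7 normal livers and was at least 469-fold higher. It was at least 268-fold higher in myc-lucOS-bcat. Sftpc, a lung surfactant gene, was at 21.4 CPM here, and tissue carryover was not tested. The counts were 3581 genes higher and 2366 lower.

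The myc-lucOS-bcat tumors likewise had high growth genes and low interferon genes. Ctnnb1 stood at 2438 against 316 CPM (log2 3.01 ± 0.26, adjusted p = 8.51e-10, 3 of 3) and Myc at 236 against 9.29 CPM (log2 4.72 ± 0.52, adjusted p = 5.92e-08, 3 of 3). Cdk1 rose (log2 4.62 ± 0.31, adjusted p = 1.41e-11, 3 of 3), and of 25 proliferation genes 25 rose (25 adjusted over the list alone). Npm1 rose (log2 2.64 ± 0.28, adjusted p = 4.45e-08, 3 of 3), and of 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone). Isg15, an interferon-induced ubiquitin-like protein, fell by 3.47 ± 0.65 (adjusted p = 0.000141, 3 of 3). Of the 25 interferon and antigen presentation genes 16 fell (16 adjusted over the list alone, median log2 change -1.75, camera adjusted p = 1.48e-08, adjusted p = 0.569 with an estimated correlation). The means of macrophage, T and NK cell and endothelial genes also lay below every normal liver, with none of these lists called (camera adjusted p = 0.204, 0.0779 and 0.0625). C-reactive protein (Crp) was at 15.1 against 422 CPM (log2 -4.74 ± 1.21, adjusted p = 0.00303, 3 of 3). Among the 15 acute phase genes 6 fell (6 adjusted over the list alone, median log2 change -2.30, camera adjusted p = 0.00438, adjusted p = 0.702 with an estimated correlation). Of 25 hepatocyte genes 15 fell (17 adjusted over the list alone). Scd2, a stearoyl-CoA desaturase, rose (log2 6.54 ± 0.60, adjusted p = 2.49e-09, 3 of 3), and of 15 oncofetal genes 7 rose (7 adjusted over the list alone). Calls numbered 3753 higher and 2313 lower.

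MYC;CTNNB1 tumors had the most calls among the 9 genotypes, with high Wnt feedback genes and low hepatocyte genes. Apcdd1, a membrane inhibitor of Wnt signaling, rose from 0.124 to 393 CPM (log2 11.45 ± 1.15, adjusted p = 5.56e-09, 3 of 3) and Tcf7, a Wnt transcription factor, from 2.76 to 98.7 CPM (log2 5.17 ± 0.61, adjusted p = 1.06e-07, 3 of 3). Among 15 Wnt feedback genes 9 rose and 1 fell (9 rose and 1 fell when adjusted over the list alone, median log2 change 4.02, camera adjusted p = 0.0199, adjusted p = 0.612 with an estimated correlation). Pericentral genes, which depend on Wnt in normal liver, went the other way. Of the 16 pericentral genes 12 fell (13 adjusted over the list alone, median log2 change -4.35, camera adjusted p = 0.00101, adjusted p = 0.614 with an estimated correlation). The hepatocyte transcription factor gene Cebpa went from 479 to 21.9 CPM (log2 -4.42 ± 0.49, adjusted p = 2.71e-08, 3 of 3), and of 25 hepatocyte genes 25 fell (25 adjusted over the list alone). Stab2, a sinusoidal scavenger receptor, fell by 3.13 ± 0.66 (adjusted p = 0.000221, 3 of 3) while Cd34, of capillary endothelium, rose (log2 2.50 ± 0.37, adjusted p = 2.63e-06, 3 of 3), and of 15 endothelial genes 1 rose and 9 fell (1 rose and 9 fell when adjusted over the list alone). All 25 proliferation and 20 ribosome biogenesis genes rose (all adjusted over the list alone). Igf2bp3, a fetal RNA-binding protein gene, rose (log2 5.25 ± 0.89, adjusted p = 1.67e-05, 3 of 3), and of 15 oncofetal genes 13 rose (13 adjusted over the list alone). Fzd10, a Wnt receptor, had no reads in normal liver and was at least 1704-fold higher. The test called 5839 genes higher and 4361 lower.

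In MYC;sg-Axin1 tumors growth genes rose while most hepatocyte genes were not called. Axin1 itself was at 39.3 against 38.5 CPM (log2 0.06 ± 0.15, adjusted p = 0.797). Birc5 (survivin) rose (log2 5.48 ± 0.38, adjusted p = 2.13e-11, 3 of 3), and of 25 proliferation genes 25 rose (25 adjusted over the list alone). Of 20 ribosome biogenesis genes 19 rose (20 adjusted over the list alone). Slc1a2, a pericentral glutamate transporter, was at 0.343 against 164 CPM (log2 -8.81 ± 2.13, adjusted p = 0.00264, 3 of 3). Among 16 pericentral genes 7 fell (9 adjusted over the list alone, median log2 change -3.32, camera adjusted p = 3.74e-05, adjusted p = 0.648 with an estimated correlation). Of the 25 hepatocyte genes 4 fell (4 adjusted over the list alone). Igf2 reached 1564 CPM (log2 9.27 ± 1.04, adjusted p = 1.19e-07, 3 of 3), and of 15 oncofetal genes 6 rose (6 adjusted over the list alone). Of 12 pancreatic acinar genes 11 rose (12 adjusted over the list alone, median log2 change 13.65, or 12.18 with members without counts on one side at their bound, camera adjusted p = 0.0216, adjusted p = 0.648 with an estimated correlation). These genes were read mainly in MYC;sg-Axin1 tumor 2 (Ctrb1 1032 CPM, Pnlip 572 CPM), and without it, normal liver 4 and CTNNB1;Tert tumor 2 the camera sign of that list turned (adjusted p = 0.801), with 2 members called higher and 0 lower. Calls numbered 2989 higher and 1493 lower.

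MYC;sg-Kmt2b tumors had low Wnt feedback and pericentral genes, as had MYC;sg-Kmt2c and MYC;sg-p53 tumors (Axin2 at most 1.48 and 0.691 CPM). Axin2, a classical Wnt feedback gene, stood at 0.360 against 7.60 CPM (log2 -4.30 ± 0.96, adjusted p = 0.000643, 4 of 4), and Lgr5, a Wnt-amplifying receptor, fell by 6.45 ± 1.41 (adjusted p = 0.000507, 4 of 4). Among 15 Wnt feedback genes 7 fell (7 adjusted over the list alone, median log2 change -2.55, camera adjusted p = 0.0149, adjusted p = 0.673 with an estimated correlation). Lect2, a secreted protein of the pericentral list, went from 136 to 0.611 CPM (log2 -7.67 ± 1.53, adjusted p = 0.000194, 4 of 4). Of the 16 pericentral genes 13 fell (13 adjusted over the list alone, median log2 change -5.01, camera adjusted p = 1.6e-06, adjusted p = 0.673 with an estimated correlation). Cdk1 rose (log2 5.49 ± 0.31, adjusted p = 3.21e-13, 4 of 4), and of 25 proliferation genes 25 rose (25 adjusted over the list alone). Higher were 20 of 20 ribosome biogenesis and 9 of 15 oncofetal genes, and lower 23 of 25 hepatocyte genes. These counts held over each list alone. Mcpt4 and Cpa3, proteases of mast cells, had no reads in the 7 normal livers and were at least 1791-fold and 1504-fold higher. Kmt2b was at 64.6 against 80.6 CPM (log2 -0.23 ± 0.20, adjusted p = 0.357). The test called 4342 genes higher and 3230 lower.

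MYC;sg-Kmt2c tumors paired high growth genes with low acute phase genes. Aurka rose from 2.28 to 100.2 CPM (log2 5.56 ± 0.32, adjusted p = 4.9e-13, 3 of 3), and of 25 proliferation genes 25 rose (25 adjusted over the list alone). Nop58, a snoRNP protein gene, rose (log2 2.50 ± 0.23, adjusted p = 1e-09, 3 of 3), and of 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone). Pkm, the pyruvate kinase gene of proliferating tissue, was at 1796 against 31.8 CPM (log2 5.87 ± 0.59, adjusted p = 7.92e-09, 3 of 3). Among 13 glycolysis genes 8 rose (9 adjusted over the list alone, median log2 change 1.62, camera adjusted p = 3e-04, adjusted p = 0.584 with an estimated correlation). Orm1, an acute phase glycoprotein, was at 10.5 against 1283 CPM (log2 -6.90 ± 1.38, adjusted p = 0.000199, 3 of 3). Of the 15 acute phase genes 1 rose and 13 fell (1 rose and 13 fell when adjusted over the list alone, median log2 change -3.96, camera adjusted p = 0.000427, adjusted p = 0.586 with an estimated correlation). Tdo2, which breaks down tryptophan in hepatocytes, fell by 8.27 ± 1.65 (adjusted p = 0.000198, 3 of 3), and of 25 hepatocyte genes 23 fell (23 adjusted over the list alone). Scd2 rose (log2 7.54 ± 0.62, adjusted p = 1.85e-10, 3 of 3), and of 15 oncofetal genes 9 rose (10 adjusted over the list alone). Lhx1, a developmental homeobox gene, had no reads in normal liver and was at least 301-fold higher. Kmt2c was at 49.4 against 69.2 CPM (log2 -0.45 ± 0.27, adjusted p = 0.176), and was called lower by voom (log2 -0.50, adjusted p = 0.0141) and with only these groups fitted (log2 -0.45, adjusted p = 0.0351). Calls numbered 4041 higher and 3428 lower.

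For MYC;sg-p53 tumors replicates 1 and 3 were used, because labels and contents of the library labelled replicate 2 conflict. Trp53 was at 24.9 against 26.7 CPM in normal liver (log2 -0.01 ± 0.25, adjusted p = 0.992), and Myc at 271 against 9.29 CPM (log2 4.93 ± 0.55, adjusted p = 6.53e-08, 2 of 2). Shbg, the sex hormone binding globulin gene, rose from 0.0401 to 30.6 CPM (log2 9.25 ± 1.52, adjusted p = 2.91e-05, 2 of 2). Cad, which starts pyrimidine synthesis, rose (log2 3.88 ± 0.39, adjusted p = 1.19e-08, 2 of 2), and of 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone). Among the 25 proliferation genes 25 rose (25 adjusted over the list alone). B2m fell by 3.01 ± 0.54 (adjusted p = 9.74e-05, 2 of 2). Of 25 interferon and antigen presentation genes 15 fell (16 adjusted over the list alone, median log2 change -2.13, camera adjusted p = 4e-08, adjusted p = 0.528 with an estimated correlation). Among 25 hepatocyte genes 10 fell and of 15 oncofetal genes 9 rose (18 and 9 adjusted over each list alone). Calls numbered 3560 higher and 2140 lower, and 2528 in all without MYC;sg-p53 tumor 1, where the lone tumor is assumed to vary like the other groups.

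MYC;Tert tumors had high fetal and Notch genes, and their pericentral genes differed from tumor to tumor. Myc was at 169 against 9.29 CPM (log2 4.15 ± 0.51, adjusted p = 5.27e-07, 3 of 3) and Tert at 231 against 17.1 CPM (log2 3.73 ± 0.54, adjusted p = 7.07e-06, 3 of 3). The receptor gene Notch3 rose (log2 3.49 ± 0.44, adjusted p = 8.04e-07, 3 of 3) and so did Hey1, a Notch target (log2 3.82 ± 0.55, adjusted p = 5.62e-06, 3 of 3). Of the 11 Notch genes 8 rose (8 adjusted over the list alone, median log2 change 2.12, camera adjusted p = 0.0104, adjusted p = 0.422 with an estimated correlation). Cdkn1a, a cell cycle inhibitor induced by p53, was at 56.5 against 1.78 CPM (log2 4.82 ± 0.55, adjusted p = 1.52e-07, 3 of 3). Among the 20 p53 targets 16 rose (16 adjusted over the list alone, median log2 change 1.80, camera adjusted p = 0.000121, adjusted p = 0.31 with an estimated correlation). Pericentral genes had a median above 0 while the test pointed down. Of 16 pericentral genes 1 fell (0 adjusted over the list alone, median log2 change 0.21, camera adjusted p = 5.07e-05, adjusted p = 0.422 with an estimated correlation). Glul, the glutamine synthetase of cells around the central vein, was at 74.7, 249.7 and 9026 CPM in replicates 1, 2 and 3. Igf2 reached 383 CPM (log2 7.15 ± 0.97, adjusted p = 2.51e-06, 3 of 3), and of 15 oncofetal genes 14 rose (14 adjusted over the list alone). Among 25 hepatocyte genes 13 fell (16 adjusted over the list alone). All 25 proliferation and 20 ribosome biogenesis genes rose (all adjusted over the list alone). The test called 4997 genes higher and 2406 lower, or 4468 in all without MYC;Tert tumor 1.

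Tumors with CTNNB1 (12 libraries of 4 genotypes) were set against the other 15. All 15 carry MYC and CTNNB1;Tert does not, so the contrast also holds a difference in MYC. The 6 luc tumors alone have the title prefix, so a batch is part of it. Wnt feedback genes were higher, with Tcf7 at 32.7 against 2.25 CPM (log2 3.82 ± 0.40, adjusted p = 1.75e-06, 4 of 12), Axin2 (log2 3.93 ± 0.53, adjusted p = 8.11e-05, 2 of 12) and Lef1 (log2 3.71 ± 0.59, adjusted p = 0.000355, 3 of 12). Among the 15 Wnt feedback genes 10 rose (13 rose and 1 fell when adjusted over the list alone, median log2 change 3.19, camera adjusted p = 3.39e-10, adjusted p = 0.152 with an estimated correlation). Ctnnb1 itself rose (log2 1.88 ± 0.16, adjusted p = 6.04e-08, 11 of 12). Of 16 pericentral genes 4 rose (6 adjusted over the list alone, median log2 change 0.95, camera adjusted p = 0.000317, adjusted p = 0.834 with an estimated correlation). Sds, a serine dehydratase of periportal cells, was at 4.97 against 132 CPM (log2 -5.25 ± 1.04, adjusted p = 0.00176, 6 of 12) and Gls2 at 38.2 against 145 CPM (log2 -2.03 ± 0.44, adjusted p = 0.00351, 4 of 12). Among 16 periportal genes 10 fell (11 adjusted over the list alone, median log2 change -1.83, camera adjusted p = 3.72e-07, adjusted p = 0.47 with an estimated correlation). Krt23, a keratin of the biliary list, rose (log2 2.82 ± 0.70, adjusted p = 0.0084, 7 of 12). Of the 14 biliary progenitor genes 3 rose and 1 fell (6 rose and 1 fell when adjusted over the list alone, median log2 change 1.01, camera adjusted p = 0.0214, adjusted p = 0.834 with an estimated correlation), and the camera adjusted p was 0.0506 without normal liver 4, CTNNB1;Tert tumor 2 and MYC;sg-Axin1 tumor 2. Among the 25 proliferation genes 11 fell (19 adjusted over the list alone, median log2 change -0.56, camera adjusted p = 2.27e-07, adjusted p = 0.774 with an estimated correlation), Birc5 among those that fell (log2 -0.97 ± 0.21, adjusted p = 0.00278). Genotypes went apart here too: the list mean was 3.93, 4.65 and 4.397 in CTNNB1;Tert and 7.04, 6.95 and 6.72 in MYC;CTNNB1 tumors, with 5.01 to 7.15 in the 15 others. Calls numbered 1140 higher and 1298 lower, and 1576 in all with the MYC;sg-p53 libraries as labelled.

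**Figure D3:**
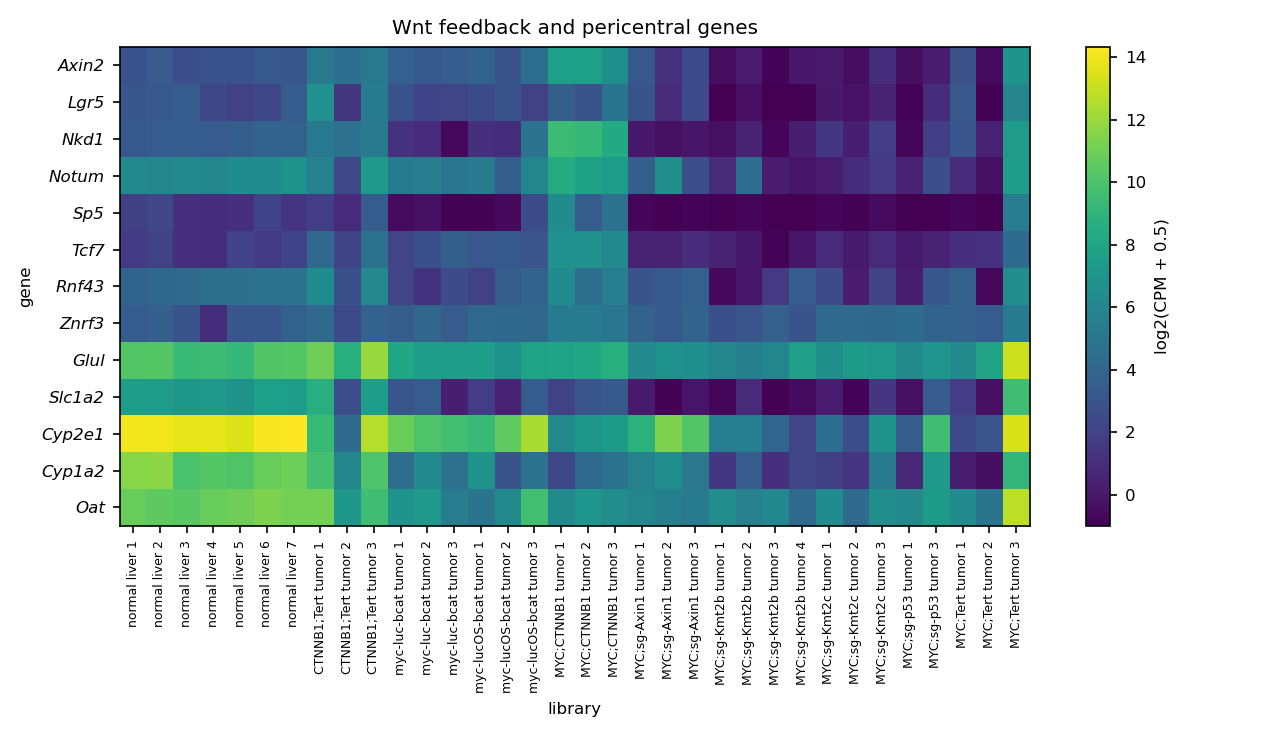
Levels of 8 Wnt feedback genes (top) and 5 pericentral genes, as log2(CPM + 0.5), in each normal liver and each tumor used, 1 column per library. Nkd1 is highest in MYC;CTNNB1 tumors (720.5, 586 and 332 CPM) and Glul in MYC;Tert tumor 3 (9026 CPM).

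MYC;CTNNB1 was set against MYC;sg-Axin1 because either lesion is aimed at beta-catenin. Wnt feedback genes stood far apart, with Apcdd1 at 393 against 0.243 CPM (log2 10.63 ± 1.56, adjusted p = 0.000114, 3 of 3) and Tcf7 at 98.7 against 1.08 CPM (log2 6.52 ± 0.92, adjusted p = 8.42e-05, 3 of 3). Of 15 Wnt feedback genes 10 rose and 1 fell (10 rose and 1 fell when adjusted over the list alone, median log2 change 4.48, camera adjusted p = 1.58e-05, adjusted p = 0.59 with an estimated correlation). Msx2 and Sp7, genes of bone-forming cells, had no reads in MYC;sg-Axin1 tumors and were at least 1292-fold and 1230.0-fold higher. Cebpa was at 21.9 against 277 CPM (log2 -3.67 ± 0.49, adjusted p = 6.81e-05, 3 of 3). Among 25 hepatocyte genes 23 fell (23 adjusted over the list alone, median log2 change -4.44, camera adjusted p = 1.32e-08, adjusted p = 0.59 with an estimated correlation). Uroc1, of histidine breakdown, fell by 6.60 ± 1.29 (adjusted p = 0.000689, 3 of 3), and of 16 periportal genes 11 fell (12 adjusted over the list alone). Of the 16 pericentral genes 2 fell (1 adjusted over the list alone), and of 14 biliary progenitor genes 5 rose and 2 fell (6 rose and 2 fell when adjusted over the list alone). Mcm2, a replication helicase subunit, was higher (log2 1.60 ± 0.32, adjusted p = 9e-04, 3 of 3), and of 25 proliferation genes 6 rose (6 adjusted over the list alone). Calls numbered 2960 higher and 3040 lower, or 3887 in all without MYC;sg-Axin1 tumor 2. The balance turned to 3351 and 2762 with the size factors of DESeq2, 3586 and 3054 by DESeq2 and 3381 and 2986 by voom. The median over all genes moved from 0.04 to 0.15 with the size factors of DESeq2.

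MYC;CTNNB1 and CTNNB1;Tert share CTNNB1 and differ in its partner. Myc was at 623 against 36.1 CPM (log2 4.21 ± 0.71, adjusted p = 5.61e-05, 3 of 3) and Tert at 20.02 against 1842 CPM (log2 -6.49 ± 0.85, adjusted p = 3.81e-06, 3 of 3). Polr1b, an RNA polymerase I subunit gene, rose (log2 3.14 ± 0.34, adjusted p = 5.32e-07, 3 of 3). Among the 20 ribosome biogenesis genes 20 rose (20 adjusted over the list alone, median log2 change 2.53, camera adjusted p = 5.9e-15, adjusted p = 0.458 with an estimated correlation). B2m was at 54.5 against 1121 CPM (log2 -4.32 ± 0.52, adjusted p = 1.57e-06, 3 of 3) and Tap2, a peptide transporter of class I loading, fell by 3.65 ± 0.52 (adjusted p = 9.26e-06, 3 of 3). Of 25 interferon and antigen presentation genes 23 fell (24 adjusted over the list alone, median log2 change -3.16, camera adjusted p = 3.21e-11, adjusted p = 0.458 with an estimated correlation). Immune cell genes were lower too, and the contrast does not separate these from the interferon genes. Of the 13 neutrophil genes 10 fell (12 adjusted over the list alone, median log2 change -5.58, camera adjusted p = 0.00375, adjusted p = 0.877 with an estimated correlation). Of the 19 T and NK cell genes 4 fell (0 adjusted over the list alone, median log2 change -1.53, camera adjusted p = 0.0172, adjusted p = 0.877 with an estimated correlation). Of the 11 B and plasma cell genes 9 fell (9 adjusted over the list alone, median log2 change -4.47, camera adjusted p = 0.0176, adjusted p = 0.877 with an estimated correlation). CTNNB1;Tert tumor 2 was the highest of the 6 tumors in neutrophil and macrophage means (4.39 and 6.67). Without it, normal liver 4 and MYC;sg-Axin1 tumor 2 22 interferon and antigen presentation genes fell, with the list still called, and the camera adjusted p was 0.106 for neutrophil, 0.032 for T and NK cell and 0.158 for B and plasma cell genes. Spp1 (osteopontin) was at 40.7 against 1728 CPM (log2 -5.32 ± 1.07, adjusted p = 0.00036, 3 of 3), and of 14 biliary progenitor genes 2 rose and 2 fell (2 rose and 2 fell when adjusted over the list alone). Wif1, a secreted Wnt inhibitor, was higher (log2 10.76 ± 1.86, adjusted p = 7.52e-05, 3 of 3). Among 15 Wnt feedback genes 7 rose and 1 fell (7 rose and 1 fell when adjusted over the list alone, median log2 change 1.90, camera adjusted p = 0.022, adjusted p = 0.877 with an estimated correlation), and its camera adjusted p was 0.158 without normal liver 4, CTNNB1;Tert tumor 2 and MYC;sg-Axin1 tumor 2. Slc13a3, a dicarboxylate transporter, was at 1.93 against 166 CPM (log2 -6.39 ± 1.41, adjusted p = 0.000804, 3 of 3), and of 16 pericentral genes 12 fell (13 adjusted over the list alone). Of 16 periportal genes 6 fell and of 25 proliferation genes 25 rose (4 and 25 adjusted over each list alone). The test called 3380 genes higher and 4059 lower, against 1764 and 1689 (3453 in all) with only these 6 libraries fitted and 3508 and 3436 by voom.

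MYC;CTNNB1 and MYC;Tert share MYC. The Y-linked mean was below 0 in each MYC;Tert tumor but 3.51 and 4.70 in MYC;CTNNB1 tumors 2 and 3, so sex is part of this contrast. With the term for Y-linked reads 2370 genes were called. Apcdd1 was at 393 against 5.27 CPM (log2 6.32 ± 1.28, adjusted p = 0.00494, 3 of 3) and Tcf7 at 98.7 against 7.82 CPM (log2 3.70 ± 0.80, adjusted p = 0.0063, 3 of 3). Of 15 Wnt feedback genes 4 rose (5 rose and 1 fell when adjusted over the list alone, median log2 change 2.003, or 1.72 with members without counts on one side at their bound, camera adjusted p = 2.52e-06, adjusted p = 0.438 with an estimated correlation). Trp53 was higher in MYC;CTNNB1 (log2 1.09 ± 0.26, adjusted p = 0.00911, 3 of 3), and Tert lower (log2 -3.49 ± 0.74, adjusted p = 0.00587, 3 of 3). Cebpa fell by 2.14 ± 0.46 (adjusted p = 0.00602, 3 of 3). Among 25 hepatocyte genes 18 fell (25 adjusted over the list alone, median log2 change -3.82, camera adjusted p = 0.000151, adjusted p = 0.926 with an estimated correlation). Their mean was 3.18, 4.35 and 5.34 in MYC;CTNNB1 tumors against 2.50, 7.31 and 9.56 in MYC;Tert tumors, so MYC;Tert tumor 1 stands the other way. Fabp4, a fatty acid carrier gene, was lower (log2 -2.97 ± 0.51, adjusted p = 0.00222, 3 of 3). Of the 7 adipocyte genes 3 fell (6 adjusted over the list alone, median log2 change -6.37, camera adjusted p = 0.0057, adjusted p = 0.438 with an estimated correlation). Among the 16 pericentral genes 7 fell (14 adjusted over the list alone), which rests on MYC;Tert tumor 3 (mean 9.46). The means of MYC;Tert tumors 1 and 2 (1.48 and 2.54) lay below those of MYC;CTNNB1 tumors (3.13, 3.80 and 4.27). Of 16 periportal genes 7 fell and of 14 biliary progenitor genes 0 were called (11 and 0 adjusted over each list alone). Mcm2 was higher (log2 1.51 ± 0.32, adjusted p = 0.00602, 3 of 3), and of 25 proliferation genes 11 rose (21 adjusted over the list alone). Calls numbered 1032 higher and 1730 lower, in all 424 without MYC;CTNNB1 tumor 1, 599 without MYC;CTNNB1 tumor 2, and 4853, 1762 and 667 without MYC;Tert tumors 1, 2 and 3. With only these 6 libraries fitted edgeR called 0 genes, with 2612 at an unadjusted p under 0.05, while in the joint fit DESeq2 called 3808 and voom 3043, where the balance turned to 1711 higher and 1332 lower.

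CTNNB1;Tert and MYC;Tert share Tert. The Y-linked mean was below 0 in each MYC;Tert tumor but 5.45 and 5.64 in CTNNB1;Tert tumors 2 and 3, so sex is part of this contrast. With the term for Y-linked reads 1686 genes were called. Dkc1 fell by 2.45 ± 0.33 (adjusted p = 0.000112, 3 of 3) and Rrp12, an rRNA processing factor, fell by 2.46 ± 0.35 (adjusted p = 0.000157, 3 of 3). Among 20 ribosome biogenesis genes 18 fell (20 adjusted over the list alone, median log2 change -1.72, camera adjusted p = 1.26e-19, adjusted p = 0.219 with an estimated correlation). The mitotic kinesin gene Kif11 was at 14.04 against 72.6 CPM (log2 -2.37 ± 0.42, adjusted p = 0.000973, 3 of 3), and of 25 proliferation genes 18 fell (22 adjusted over the list alone). B2m was at 1121 against 234 CPM (log2 2.27 ± 0.47, adjusted p = 0.00317, 3 of 3) and Iigp1, an interferon-inducible GTPase, at 275 against 15.7 CPM (log2 4.14 ± 0.95, adjusted p = 0.00624, 2 of 3). Of the 25 interferon and antigen presentation genes 13 rose (16 adjusted over the list alone, median log2 change 1.87, camera adjusted p = 8.41e-10, adjusted p = 0.613 with an estimated correlation). Among 19 T and NK cell genes 0 were called (0 adjusted over the list alone, median log2 change 1.49, camera adjusted p = 0.000971, adjusted p = 0.753 with an estimated correlation). Akr1c18, a progesterone-inactivating reductase, was at 341 against 0.234 CPM (log2 10.48 ± 1.80, adjusted p = 0.000878, 3 of 3). In the pericentral list the median lay below 0 while the test pointed up. Among the 16 pericentral genes 0 were called (0 adjusted over the list alone, median log2 change -0.46, camera adjusted p = 0.00389, adjusted p = 0.753 with an estimated correlation). Of 15 Wnt feedback genes 1 fell (0 adjusted over the list alone). Among 16 periportal genes 1 rose and 3 fell, and of 14 biliary progenitor genes 2 rose (as many adjusted over each list alone). The test called 1047 genes higher and 1414 lower. With only these 6 libraries fitted edgeR called 0, with 1561 at an unadjusted p under 0.05, while in the joint fit DESeq2 called 3498 and voom 646, with the balance turned to 362 higher and 284 lower.

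The lucOS cargo, a luciferase joined to T cell antigens in earlier use of such vectors, was compared with luc. No list of immune cell or interferon genes was called between the 3 tumors of each kind. Of the 19 T and NK cell, 15 macrophage and 25 interferon and antigen presentation genes 0 were called (0 adjusted over each list alone). The last list had a mean and test below 0 and a median log2 change of 0.03 (camera adjusted p = 0.7). Of 10 red cell genes 0 were called (0 adjusted over the list alone, median log2 change 0.96, camera adjusted p = 0.0345, adjusted p = 0.967 with an estimated correlation). Among 15 Wnt feedback genes 0 were called (2 rose when adjusted over the list alone, median log2 change 0.54, camera adjusted p = 0.00782, adjusted p = 0.967 with an estimated correlation). Of the 25 proliferation genes 0 were called (0 adjusted over the list alone, median log2 change -0.34, camera adjusted p = 2.55e-07, adjusted p = 0.967 with an estimated correlation). Ctnnb1 was at 2438 against 2157 CPM (log2 0.16 ± 0.33, adjusted p = 1) and Myc at 236 against 171 CPM (log2 0.46 ± 0.62, adjusted p = 1). The test of edgeR called 0 genes, with 248 at an unadjusted p under 0.05, while voom called 0 and DESeq2 23, of which 16 were higher and 7 lower. On simulated data of this size edgeR recovered 7% of 2-fold and 44% of 4-fold changes.

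MYC;sg-Kmt2b and MYC;sg-Kmt2c, which target related methyltransferases, differed in few genes. Bhlhb9, a basic helix-loop-helix gene by name, was at 0.469 against 23.1 CPM (log2 -5.59 ± 0.40, adjusted p = 1.12e-09, 4 of 4). Rps6ka6, a ribosomal S6 kinase gene, was at 0.0330 against 35.3 CPM (log2 -9.72 ± 1.31, adjusted p = 0.000181, 4 of 4), and Jph1, a junctophilin gene, fell by 6.43 ± 1.12 (adjusted p = 0.00335, 4 of 4). Kmt2c was at 51.8 against 49.4 CPM (log2 0.11 ± 0.29, adjusted p = 0.915) and Kmt2b at 64.6 against 107.9 CPM (log2 -0.69 ± 0.24, adjusted p = 0.159). Kmt2b was called lower by voom (log2 -0.79, adjusted p = 0.0183) and without MYC;sg-Kmt2b tumor 3 (log2 -0.93, adjusted p = 0.0371). Among the 15 stellate cell and matrix genes 0 were called (0 adjusted over the list alone, median log2 change -1.64, camera adjusted p = 0.000968, adjusted p = 0.815 with an estimated correlation). Among 15 oncofetal genes 0 were called (1 fell when adjusted over the list alone), and of 25 proliferation genes 0 were called (0 adjusted over the list alone). The test called 129 genes higher and 98 lower, against 812 in all by DESeq2 and 1004 by voom. The balance turned to 38 and 43 with a term for the S index and to 30 and 58 with only these groups fitted. The total was 122, 97 and 483 without MYC;sg-Kmt2b tumors 1, 2 and 3, and 56, 68 and 48 without MYC;sg-Kmt2c tumors 1, 2 and 3.

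MYC;sg-p53 tumors 1 and 3 were set against the 13 other tumors without CTNNB1. Trp53 was at 24.9 against 94.96 CPM (log2 -1.85 ± 0.28, adjusted p = 0.00309, 2 of 2), the 1 gene called lower, a call lost without MYC;sg-p53 tumor 1 (log2 -1.67, adjusted p = 0.316). Of the 20 p53 targets 0 were called (5 fell when adjusted over the list alone, median log2 change -0.69, camera adjusted p = 4.61e-07, adjusted p = 0.444 with an estimated correlation). Axin1 was at 66.2 against 49.9 CPM (log2 0.50 ± 0.16, adjusted p = 0.355), and was called higher with the MYC;sg-p53 libraries as labelled (log2 0.54, adjusted p = 0.0172). Among the 25 proliferation genes 0 were called (0 adjusted over the list alone). The test called 14 genes higher and 1 lower. The total was 7, 7 and 9 without MYC;sg-Axin1 tumors 1, 2 and 3, 6 and 9 without MYC;sg-Kmt2c tumors 1 and 3, 32 and 27 without MYC;Tert tumors 1 and 2, and 3 and 63 without MYC;sg-p53 tumors 1 and 3. With the library labelled MYC;sg-p53 tumor replicate 2 included 674 genes were called, with DESeq2 43 (17 higher and 26 lower, so the balance turned) and with a term for Y-linked reads 3. With only these groups fitted edgeR called 0, with 746 at an unadjusted p under 0.05.

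MYC;CTNNB1 and myc-luc-bcat tumors carry by name the same drivers, with the title prefix as a possible batch. The Y-linked mean was below 0 in each myc-luc-bcat but 3.51 and 4.70 in MYC;CTNNB1 tumors 2 and 3, so sex is part too. The Y-linked term gave 4507 calls. Whether the delivered copies are human or mouse is not given, so levels of drivers need not compare. Ctnnb1 was at 978 against 2157 CPM (log2 -1.17 ± 0.33, adjusted p = 0.0108, 3 of 3), while Nkd1, a Wnt antagonist of the feedback list, was at 546 against 1.11 CPM (log2 8.92 ± 1.58, adjusted p = 0.000558, 3 of 3). Of 15 Wnt feedback genes 10 rose (10 adjusted over the list alone, median log2 change 3.70, camera adjusted p = 0.000105, adjusted p = 0.701 with an estimated correlation). Twist1, a mesenchymal transcription factor, rose (log2 9.30 ± 1.66, adjusted p = 0.000573, 3 of 3). Among 16 mesenchymal genes 8 rose and 1 fell (8 rose and 1 fell when adjusted over the list alone, median log2 change 2.03, camera adjusted p = 0.00971, adjusted p = 0.701 with an estimated correlation). Ibsp (bone sialoprotein) had no reads in myc-luc-bcat tumors and was at least 6222-fold higher. Tdo2 was at 6.40 against 648 CPM (log2 -6.70 ± 1.57, adjusted p = 0.00341, 3 of 3). Of the 25 hepatocyte genes 19 fell (22 adjusted over the list alone, median log2 change -3.60, camera adjusted p = 2.95e-07, adjusted p = 0.701 with an estimated correlation). Of 16 pericentral genes 2 fell and of 16 periportal genes 9 (0 and 9 adjusted over each list alone). Of 14 biliary progenitor genes 1 and of 25 proliferation genes 4 rose (0 and 3 adjusted over each list alone). Calls numbered 2169 higher and 2382 lower, 2703 in all without MYC;CTNNB1 tumor 1, 2950 without myc-luc-bcat tumor 2 and 6977 by voom. The size factors of DESeq2 moved the median over all genes from 0.07 to 0.18 and turned the balance to 2550 higher and 2127 lower. It was 2912 and 2491 by DESeq2 and 3745 and 3232 by voom.

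Cell lines (11) were set against tumors of the same 5 genotypes (16). Tdo2 was at 0.220 against 249 CPM (log2 -9.39 ± 0.63, adjusted p = 1.89e-09, 11 of 11). Of the 25 hepatocyte genes 25 fell (25 adjusted over the list alone, median log2 change -8.26, camera adjusted p = 1.18e-14, adjusted p = 0.217 with an estimated correlation). Markers of other cell types were low as well. Among the 19 T and NK cell genes 19 fell (19 adjusted over the list alone). Of 15 macrophage genes 14 fell (14 adjusted over the list alone, median log2 change -7.38, camera adjusted p = 5.12e-07, adjusted p = 0.229 with an estimated correlation). Cd5l, secreted by Kupffer cells, was at 0.315 against 69.8 CPM (log2 -9.01 ± 0.84, adjusted p = 6.09e-08, 11 of 11). Cdh5, an endothelial cadherin, fell by 7.89 ± 0.73 (adjusted p = 6.03e-08, 11 of 11). Among 15 endothelial genes 14 fell (14 adjusted over the list alone, median log2 change -5.97, camera adjusted p = 2.16e-08, adjusted p = 0.217 with an estimated correlation). Of the 15 stellate cell and matrix genes 4 rose and 5 fell (4 rose and 5 fell when adjusted over the list alone). S100a6, a calcium-binding protein gene, rose from 27.4 to 575 CPM (log2 5.30 ± 0.37, adjusted p = 2.19e-09, 10 of 11). Among the 16 mesenchymal genes 14 rose (14 adjusted over the list alone, median log2 change 2.30, camera adjusted p = 5.06e-07, adjusted p = 0.217 with an estimated correlation). Ajuba, a Hippo pathway gene, rose (log2 3.06 ± 0.18, adjusted p = 6.94e-10, 11 of 11), and of 12 YAP genes 10 rose (10 rose and 1 fell when adjusted over the list alone). Phlda3, a p53 target that restrains Akt, rose (log2 3.83 ± 0.26, adjusted p = 2.08e-09, 10 of 11), and of 20 p53 targets 14 rose and 2 fell (14 rose and 2 fell when adjusted over the list alone). Of 25 proliferation genes 9 rose (9 adjusted over the list alone). Of 16066 genes 3780 were higher and 4978 lower, and 5824 were called with the animal as a block in the 10 animals with a tumor and a line.

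**Figure D4:**
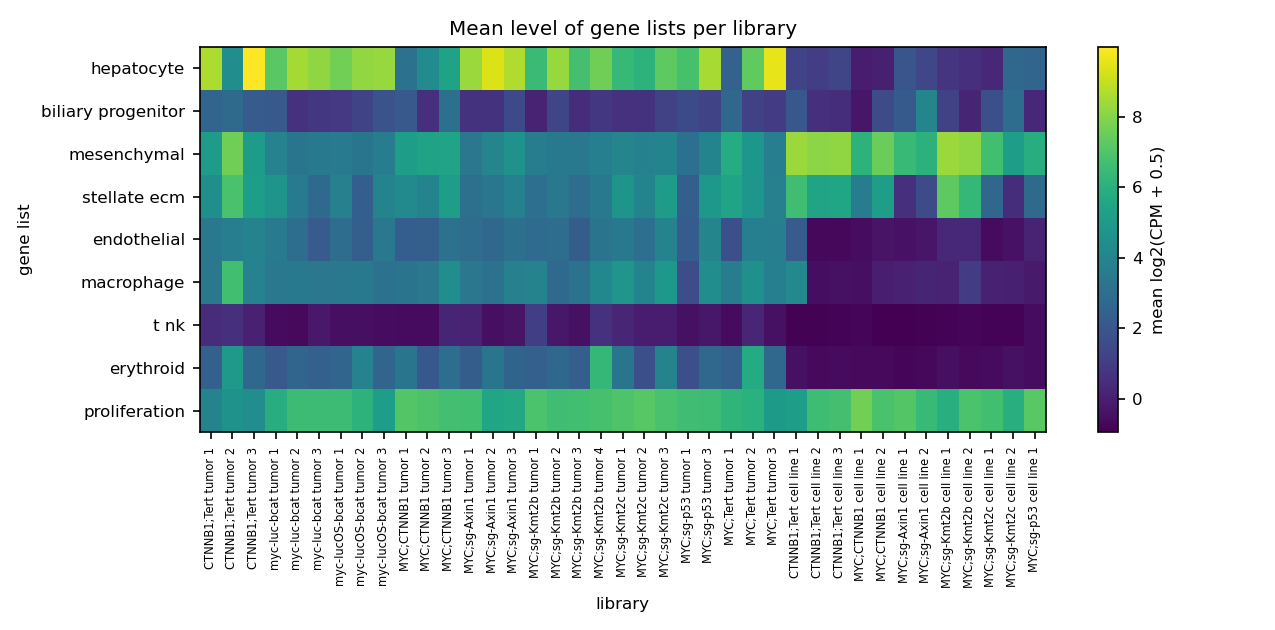
Mean level of 9 gene lists, as the mean of log2(CPM + 0.5) over the members of each list (y axis), in each tumor and each cell line used, 1 column per library. Hepatocyte, endothelial, macrophage and red cell lists are higher in tumors, and CTNNB1;Tert cell line 1 stands apart among lines in the macrophage list (C1qa 137 CPM).

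CTNNB1;Tert lines (3) were set against lines of the MYC genotypes (8). Lines 2 and 3 of CTNNB1;Tert, of 2 animals by their titles, were far closer to each other than other pairs of lines of 1 genotype (chi-square per degree of freedom 8.57, next 228.6), so whether they count as 2 replicates is open. Myh11, smooth muscle myosin, was at 980.1 against 14.2 CPM (log2 9.99 ± 0.86, adjusted p = 7.03e-07, 3 of 3) and Tagln, an actin cross-linker of smooth muscle, at 4869 against 394 CPM (log2 6.49 ± 0.95, adjusted p = 0.000145, 3 of 3). Among 15 stellate cell and matrix genes 8 rose (10 adjusted over the list alone, median log2 change 2.91, camera adjusted p = 0.000311, adjusted p = 0.745 with an estimated correlation). MYC;sg-Kmt2b lines were as high in this list (means 7.25 and 6.35 against 6.65, 5.42 and 5.51). Of 15 macrophage genes 11 rose (11 adjusted over the list alone), carried by CTNNB1;Tert line 1 (mean 4.22, below 0 in lines 2 and 3). Lats2, a Hippo kinase gene, rose (log2 1.74 ± 0.25, adjusted p = 0.000124, 3 of 3), and of 12 YAP genes 9 rose (9 adjusted over the list alone). Srebf2, a regulator of sterol synthesis, fell by 2.06 ± 0.35 (adjusted p = 0.000543, 3 of 3) and its target Sqle fell by 2.49 ± 0.47 (adjusted p = 0.00112, 3 of 3). Of the 16 lipid synthesis genes 12 fell (12 adjusted over the list alone, median log2 change -1.90, camera adjusted p = 6.3e-07, adjusted p = 0.745 with an estimated correlation). Polr1b fell by 1.91 ± 0.32 (adjusted p = 0.00043, 3 of 3), and of 20 ribosome biogenesis genes 10 fell (11 adjusted over the list alone). Myc and Trp53 were lower (log2 -2.20 ± 0.57, adjusted p = 0.00952, 3 of 3, and log2 -1.32 ± 0.23, adjusted p = 0.000564, 3 of 3). Tert was at 8.61 against 5.71 CPM (log2 0.89 ± 0.55, adjusted p = 0.268). Calls numbered 2136 higher and 1157 lower, in all 1961 without line 2 and 2089 without line 3 of CTNNB1;Tert. Voom called 7356, edgeR 1963 with only these lines fitted and 1809 with a term for the S index in the titles.

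The last comparison asked whether the step from tumor to line differed between CTNNB1;Tert and the MYC genotypes, as a difference of differences. Myh11 rose more in CTNNB1;Tert (log2 9.22 ± 1.34, adjusted p = 0.00203), while Tert fell more (log2 -5.39 ± 0.87, adjusted p = 0.00355) and so did Glul (log2 -5.34 ± 0.91, adjusted p = 0.00414). Sqle and Idi1, of cholesterol synthesis, moved lower (log2 -4.21 ± 0.59, adjusted p = 0.00158, and log2 -4.51 ± 0.80, adjusted p = 0.00478). Among the 16 lipid synthesis genes 11 fell (14 adjusted over the list alone, median log2 change -2.64, camera adjusted p = 3.92e-07, adjusted p = 0.485 with an estimated correlation). Aurka and Aurkb, mitotic kinases, rose more (log2 2.61 ± 0.55, adjusted p = 0.0108, and log2 2.34 ± 0.51, adjusted p = 0.012), and of 25 proliferation genes 17 rose (23 adjusted over the list alone). Tcf7 moved lower (log2 -5.96 ± 1.15, adjusted p = 0.00804). Of 14 Wnt feedback genes 3 fell (5 adjusted over the list alone, median log2 change -3.50, camera adjusted p = 0.000811, adjusted p = 0.485 with an estimated correlation). The test of edgeR called 648 genes higher and 838 lower (43.6% higher), against 1004 and 590 (63.0% higher) with length offsets, where the median over all genes went from -0.17 to 0.07. The balance also turned with the size factors of DESeq2 (806 and 723), with the MYC;sg-p53 libraries as labelled (560.0 and 398) and without normal liver 4, CTNNB1;Tert tumor 2 and MYC;sg-Axin1 tumor 2 (1114 and 1101). The total was 2235, 449 and 480 without CTNNB1;Tert lines 1, 2 and 3, 800 without CTNNB1;Tert tumor 1, 2851 by DESeq2, 4871 by voom and 958 with the MYC;sg-p53 libraries as labelled. With the animal as a block in 10 animals edgeR called 0, with 2793 at an unadjusted p under 0.05, against 149 in the same 20 libraries without that term.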

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

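All tests weighed in this part were chosen after the results were seen, apart from the difference of differences between tumors and lines.

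In groups of 4 to 10 libraries, 10 of 76 Dixon tests marked a library far from the others, where chance marks about 1 in 20. Normal liver 4 had the lowest depth (2.30 M reads, next 31.6), the fewest detected genes (12053) and the lowest mean log2 CPM of ribosome biogenesis (5.35) and p53 target genes (1.89). Normal liver 1 had the highest macrophage mean (5.20). MYC;sg-Kmt2b tumor 2 had the lowest Trp53 (71.6 CPM) and the highest mean of male-biased liver genes (1.75). MYC;sg-Kmt2b tumor 4 had the highest means of B and plasma cell (0.16), red cell (6.35) and pancreatic acinar genes (4.02).

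The change from tumor to line differed between CTNNB1;Tert and the MYC genotypes for 1486 genes by edgeR. With the animal as a block in 10 animals it called 0 (2793 at an unadjusted p under 0.05), and each gene named here lost its call (adjusted p at least 0.0689). As log2 differences, secreted liver and immune genes were Hpx (-5.61), Orm1 (-7.11), Cd79a (-5.63), Spp1 (-5.82), Iigp1 (-5.27) and B2m (-2.03). Drivers and immediate early genes were Tert (-5.39), Ctnnb1 (-1.16), Egr1 (-4.79) and Junb (-3.57). Wnt, pericentral and sterol genes were Tcf7 (-5.96), Rnf43 (-5.73), Glul (-5.34), Slc1a2 (-8.77), Sqle (-4.21) and Idi1 (-4.51). The largest falls were Cdh17 (-12.80), Adgrf1 (-13.18), Tnn (-12.81), Sfrp2 (-11.05) and Cxcl3 (-14.20), and the largest rises Myh11 (9.22), Ptprz1 (8.92), Asb2 (9.48), Slc39a5 (9.95) and Tex14 (8.35). Also higher were Aldh1b1 (6.30), Aurka (2.61), Aurkb (2.34), Srm (2.06), Dkc1 (1.53) and Amotl1 (3.03).

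The libraries labelled MYC;sg-p53 tumor replicate 2 and MYC;sg-p53 cell line replicate 2, in none of the comparisons, each held the content of the other tissue. The library labelled as a line had 13881 CPM of Alb (highest other line 2322) and 46.2 CPM of Hba-a1 (highest other line 0.641), and the library labelled as a tumor had 3855 CPM of Vim (highest other tumor 1905) and 0.152 CPM of C1qa (lowest other tumor 10.6). On 5 of 6 blood, immune and endothelial lists each lay in the range of the other tissue and outside its own, consistent with exchanged tissue labels. Low depth is argued against by the lower of their totals, 36.8 M reads. The tissue in the titles is argued against by these values, and the names of the deposited files give the tissue that the contents have. How the labels came to differ stays open.

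In CTNNB1;Tert lines Tert (15.7, 5.41 and 4.75 CPM) and Axin2 (4.03, 0.362 and 0.125 CPM) lay far below their tumors, while Acta2 (6455 to 12917 CPM) and Myh11 (305 to 1331 CPM) were high. Depth is argued against, since at the lowest tumor level each line would have at least 7418 Tert reads. Outgrowth of cells without the transgenes may account for it, as in 0 of the 3 lines Tert lay above all 9 lines of the MYC genotypes, MYC;sg-p53 line 1 (19.9 CPM) among them. Line 1 did lie above the 8 lines of the comparison (at most 14.1 CPM), so this support is weak. Lines 2 and 3 are near alike, as above, and need not be 2 separate cases. Loss of transgene expression with dedifferentiation of tumor cells cannot be told apart from it. Krt8 was low in lines 2 and 3 (0.780 and 1.59 CPM) and in MYC;CTNNB1 lines (at most 2.36 CPM) but at 107 CPM in line 1, and Ctnnb1 (509 to 596 CPM) did not lie above every line without CTNNB1 in its label (up to 1049.6 CPM).

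MYC;Tert tumor 3 had high Wnt feedback and pericentral genes (Axin2 121 CPM, Glul 9026 CPM). Normal liver in the sample is argued against by Glul at 7.19 times the highest normal liver. A library of a CTNNB1;Tert tumor is argued against by Myc at 4.81 times the highest of these tumors, and a MYC;CTNNB1 tumor by Tert at 11.4 times their highest. A change in the Wnt pathway of this tumor may remain as a hypothesis, which the counts did not test.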

How the results depend on the processing

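Of the 498 totals recomputed under alternatives 441 stayed within 1.5 times the reported one and 57 did not, and 7 comparisons had none that moved. Alternatives chosen after seeing the data are named above. Without normal liver 4, CTNNB1;Tert tumor 2 and MYC;sg-Axin1 tumor 2 the total for CTNNB1;Tert tumors against normal liver was 3261, and with the term for Y-linked reads that for MYC;sg-p53 against other tumors was 3. DESeq2 gave 23 for myc-lucOS-bcat against myc-luc-bcat, 812 for MYC;sg-Kmt2b against MYC;sg-Kmt2c, 43 for MYC;sg-p53 against other tumors and 2851 for the difference of differences. Voom with quality weights gave 646 for CTNNB1;Tert against MYC;Tert, 1004 for MYC;sg-Kmt2b against MYC;sg-Kmt2c, 6977 for MYC;CTNNB1 against myc-luc-bcat, 7356 for CTNNB1;Tert against MYC lines and 4871 for the difference of differences. With only the groups of the contrast fitted MYC;CTNNB1 against CTNNB1;Tert had 3453, MYC;sg-Kmt2b against MYC;sg-Kmt2c 88 and CTNNB1;Tert against MYC lines 1963. So fitted, edgeR called 0 genes in MYC;CTNNB1 against MYC;Tert (2612 at an unadjusted p under 0.05), CTNNB1;Tert against MYC;Tert (1561) and MYC;sg-p53 against other tumors (746). With the MYC;sg-p53 libraries as labelled CTNNB1 against other tumors had 1576, MYC;sg-p53 against other tumors 674 and the difference of differences 958. The S index term gave 81 for MYC;sg-Kmt2b against MYC;sg-Kmt2c and 1809 for CTNNB1;Tert against MYC lines. The cause was not tested for any of these.

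With the animal as a block in 10 animals the total was 5824 for lines against tumors, and for the difference of differences edgeR called 0 (2793 at an unadjusted p under 0.05). The same 20 libraries without the animal term gave 149 for the latter. The block kept 34 of 34 list calls at the preset correlation and 54 of 87 calls of named genes. The cause was not tested.

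Totals with 1 library left out ran from 3324 to 6435 for CTNNB1;Tert, 2528 to 5542 for MYC;sg-p53 and 4468 to 8220 for MYC;Tert against normal liver. They ran from 3887 to 5663 for MYC;CTNNB1 against MYC;sg-Axin1, 424 to 4853 against MYC;Tert and 2703 to 3969 against myc-luc-bcat. For MYC;sg-Kmt2b against MYC;sg-Kmt2c they were 48 to 483, for MYC;sg-p53 against other tumors 3 to 63, for CTNNB1;Tert against MYC lines 1961 to 3702 and for the difference of differences 449 to 2235. Of 15803 values of called named genes under alternatives 15058 stayed called in the same direction, 744 lost the call and 1 reversed, while 40 values not called at first gained a call. The reversed value was of Slc22a3 in MYC;CTNNB1 against MYC;Tert, at -6.01 with all libraries, which with 1 left out ran from -6.61 without MYC;Tert tumor 1 to 2.27 (adjusted p = 0.306) without MYC;Tert tumor 3. Of 250 list calls 0 held with an estimated correlation. At the preset correlation 247 held with the size factors of DESeq2, 240 with the term for Y-linked reads and 232 without the 3 libraries, where 17 were lost and the pancreatic acinar list in MYC;sg-Axin1 against normal liver reversed its camera sign (adjusted p = 0.801, 2 members called higher). The cause was not tested. Depth limits low genes in normal liver 4 (2.30 M reads).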

Other observations

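The splits of libraries and the levels in this part were chosen after the results were seen. CTNNB1;Tert tumor 2 stood apart from the other 2 of its genotype, with Col1a1, a matrix collagen, at 5129 CPM besides Vim and Alb. MYC;Tert tumor 1 had 847 CPM of Vim and 8.14 CPM of Hnf4a, a hepatocyte transcription factor. MYC;sg-Axin1 tumor 2 carried the pancreatic genes Ctrb1 (1032 CPM), Pnlip (572 CPM) and Cela3b (269 CPM), and MYC;sg-Kmt2b tumor 4 had Ctrb1 at 36.1 CPM and Pnlip at 17.4 CPM. CTNNB1;Tert line 1 had 137 CPM of C1qa, a macrophage gene, which was at most 2.11 CPM in the 10 other lines compared and MYC;sg-p53 line 1, and 103 CPM in the library labelled MYC;sg-p53 cell line replicate 2. Ctnnb1 was higher in myc-luc-bcat and myc-lucOS-bcat tumors than in MYC;CTNNB1 tumors, while Axin2 was lower, at 12.3, 8.98 and 10.4 CPM and at 14.9, 7.02 and 22.7 CPM against 200.03, 198 and 98.9 CPM.

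For 20 comparisons the libraries were also split at random into groups of the same sizes, 25 splits each, or all of the 10 or 35 that exist. Where only the real split, 1 of 25, gave as many calls, its total lay above every other split drawn. This does not exclude chance, since 1 of 25 is the smallest share possible and several comparisons were tried. The spread was fitted anew in each split, and mixing unlike libraries within a group can widen it and lower the other totals. Real totals against the highest other were 9380 against 1453 for all tumors, 6060 against 1611 for CTNNB1;Tert, 5947 against 8 for myc-luc-bcat, 6066 against 773 for myc-lucOS-bcat, 10200 against 1479 for MYC;CTNNB1, 4482 against 814 for MYC;sg-Axin1, 7572 against 2250 for MYC;sg-Kmt2b, 7469 against 49 for MYC;sg-Kmt2c and 7403 against 3525 for MYC;Tert, each set against normal liver. The total was 2438 against 8 for CTNNB1 against other tumors, in splits that ignored genotype and title prefix, so a batch is not excluded. For CTNNB1;Tert against MYC lines it was 3293 against 2565, also 1 of 25. That total fell below 2565 without line 2 (1961) or 3 (2089), so chance is left open there as well. Lines against tumors (8758 against 1) and the difference of differences (1486 against 322) also had 1 of 25, but these splits did not keep the tumor and line of an animal together, so they do not exclude chance. With the animal as a block in 10 animals edgeR called 5824 genes for the first and 0 for the second (2793 at an unadjusted p under 0.05). Chance cannot be excluded for MYC;sg-Kmt2b against MYC;sg-Kmt2c, where 2 of 35 splits gave as many (227 against 461). With 3 against 3 the 10 splits are too few: 6000 against 3 for MYC;CTNNB1 against MYC;sg-Axin1 and 7439 against 1565 against CTNNB1;Tert. They were 2762 against 2066 for MYC;CTNNB1 against MYC;Tert, 4551 against 2 for MYC;CTNNB1 against myc-luc-bcat, 2461 against 4212 for CTNNB1;Tert against MYC;Tert and 0 against 23 for myc-lucOS-bcat against myc-luc-bcat. As many or more came from 1, 1, 1, 1, 2 and 10 of these 10 splits, in that order.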
